A study of Oncorhynchus mykiss with 525 samples.

How the data were processed

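RTgill-W1 cells were exposed to solvent or to a chemical in 96-well plates, and the RNA of each well was tagged with a well code, pooled with up to 24 wells into a library and sequenced, per the labels' protocols, which name a QIAseq UPXome kit. The tables hold whole-number counts per Ensembl gene ID and well, which the authors deposited without normalization as far as the values show. The aligner, the counter and the genome annotation are not given in the sources used here. In such 3-prime or tagged pools, a few abundant transcripts can take much of the depth, and reads shared by near-identical gene copies can be assigned to either or both. The solvent wells appear in the table of each chemical, and 381 columns were repeats, of which 0 differed. Columns were matched to samples by the library and well in their names. The concentration in the table headers differed from the labels beyond rounding for 0 wells, and concentrations were taken as the highest one divided by 3 per step (by 2 for dca), because low values are rounded in the labels. Per the design text the pesticides were prepared in DMSO or water, and the labels do not say which; only DMSO wells were used as controls. Unexposed wells without DMSO were not used here.

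Plates and libraries follow from the labels: 24 libraries on 6 plates, 3 plates per batch. Most chemicals were pooled in other libraries than the solvent wells of their plate. The label's concentration number follows the plate row, with the highest concentration in row H for the pesticides and in row E for dca, so that concentration and row coincide within a chemical. Wells with a total under 10% of the median well (24094.8 counts) were left out, 14 in all, which left 487 wells with totals of 24620 to 786151. Between wells of 1 group, the smallest chi-square per degree of freedom over genes was 1.74 in 863 pairs, so no pair agreed within sampling noise.

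The test was edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) in R 4.3.3, two-sided, with a Benjamini-Hochberg FDR below 0.05 within each contrast. For each chemical 1 model held its concentration groups and the solvent wells of its batch; for dca both batches, with batch as a term. The trend used the slope on the concentration step in the chemical's own wells. Benchmark concentrations were fitted by least squares with linear, exponential and Hill shapes to log2 CPM with a prior count of 2, with solvent as concentration 0 and a benchmark response of 1 residual SD. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The design, the rule for named genes and the alternatives, apart from those stated as added, were fixed before the data were examined. The rule took the largest rises and falls among genes past the FDR, changed at least 2-fold, with a trend and every plate in the same direction, a mean log2 CPM of 1 or more and a gene name. None of the 44260 IDs matched the reference name table, so the rule named no gene, the planned tests of gene lists by camera were not run, and 4 IDs are given in their place.

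The labels give a passage per plate as the biological replicate, which pairs the wells of a plate. Deviations from the group means over 1833 genes correlated by a median of 0.149 between wells of different groups on the same plate, with medians of 0.0955 to 0.225 per plate, against -0.0746 between plates of a batch. A second principal component with 4.77% of the variance was explained to 83.2% by plate. The fit with the plate as a replicate block is therefore given for counts that it moved by more than 1.5 times, such as 108 genes for diz against 42. Further alternatives were DESeq2 1.42.0, no filter, the lowest concentration as control, summed solvent wells, all wells kept, wells thinned to at most 1 total, removal of the most counted IDs, and leaving out each replicate.

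The scripts were tested on simulated counts with 200 changed genes, drawn from the means and totals of the real wells with an assumed dispersion of 0.15, the same for all genes, so the shares are not those of genes with a larger spread. At the highest concentration, 4-fold changes were recovered for 71% of genes for dip, 47% for met, 43% for col, 68% for diz, 61% for mbz and 88% for dca. For 2-fold changes these shares were 19%, 1%, 6%, 11%, 11% and 34%. All recovered genes had the right sign, and 1.25% to 5.77% of the calls for these chemicals were false, and up to 7.69% in simulated trends. The simulated counts held no difference between plates or libraries, and as many genes rose as fell. These shares thus do not cover false calls from such differences in the real wells. Simulated benchmark concentrations of straight-line log2 responses at 3%, 10% and 30% of the highest concentration came back with medians of 2.90%, 10% and 27.2%.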

Results

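RNA was counted in single wells of RTgill-W1, an epithelial cell line derived from rainbow trout gill, after 24 h of exposure to pesticides in 96-well plates. The purpose stated by the submitters is to derive transcriptomic points of departure, that is, the concentrations at which gene expression starts to change. Counts were used for 501 wells from 6 plates: 39 solvent wells with DMSO (24 in batch 1 and 15 in batch 2), 18 pesticides at 8 concentrations in 3-fold steps with 3 replicates each, and the chemical coded dca at 5 concentrations in 2-fold steps with 6 replicates, 3 in each batch. Chemicals are named here by the codes of the labels, and concentrations carry no unit because the labels give none. The replicates of a pesticide come from 3 cell passages, 1 per plate. A further 24 wells of the labels, all of 1 chemical, were not analysed here.

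The total count per well had a median of 240948 and ranged from 1809 to 786151, over 44260 Ensembl gene IDs of which a median of 13579 had a count in a well. The 4 most counted IDs held 46.3% of all counts. They form 2 pairs with almost identical counts, with 17.2% and 17.1% of all counts in the first pair and 5.99% and 5.97% in the second, so how the counting shared reads within a pair is uncertain. Some chemicals had low totals at high concentrations, which coincide with a plate row. The 3 wells at the highest concentration of clp held 0.815% to 10.2% of the median total of the other wells of their library, and those of smet 0.712% to 5.01%. For col, the median well of the highest concentration held 29.1%, for met 32.7% and for thx 16.7%. The wells of dip, in contrast, held 67.3% to 113%. In all, 14 wells under 24094.8 counts were left out of the tests, among them all wells at the highest concentration of clp and smet, for which the second highest was used, and replicate 2 of col at its 4 highest concentrations. Replicate 2 of dca at its highest concentration, in batch 1, was left out as well.

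**Figure D1:**
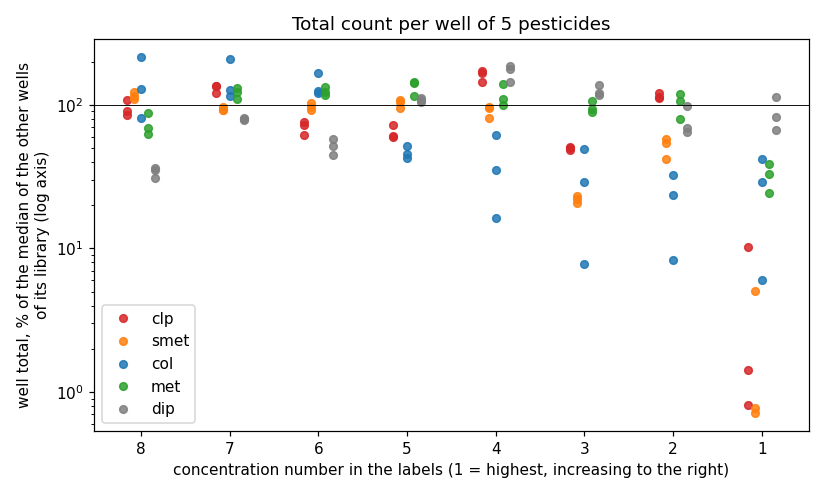
Total count of each well of 5 pesticides, in percent of the median of the other wells of its library (log axis), by concentration number of the labels, where 1 is the highest. Each point is 1 well and the horizontal line marks 100%; the wells of clp and smet at the highest concentration lie between 0.712% and 10.2%.

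The first question was which genes changed at the highest concentration of each chemical against solvent. Of 19 chemicals, dip, met and col changed many genes and the others few, where clp and smet were tested at their second highest concentration. Expression changed for 1706 genes with dip, 1031 with met and 688 with col, at a median absolute log2 fold change of 1.37, 1.85 and 2.37. The next counts were 49 genes with dca, 42 with diz and 33 with mbz. The other 13 chemicals gave 10 genes or fewer: 10 with clp, 9 each with cln and dic, 7 with smet, 5 each with ampa, car and thx, 3 with cat, 2 each with gly and per, 1 with ata, and 0 with diq and imz. All counts are from edgeR's quasi-likelihood test at a Benjamini-Hochberg FDR below 0.05. For diq, 221 of 4037 tested genes had an unadjusted p under 0.05 in edgeR and DESeq2 called 1. For imz these were 109 of 3435 and 0. By chance alone, a share of 0.05 of the tested genes falls under that p, here and in the like counts below.

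At its highest concentration of 57.64, dip raised 762 genes and lowered 944 of 4436 tested. ENSOMYG00000023930 rose by a log2 fold change of 4.28 (SE 0.37, adjusted p = 2.76e-14), from 11.4 ± 7.84 CPM (counts scaled to the total of the well) in solvent wells (SD, n = 15) to 205 ± 117 in dip wells (SD, n = 3). ENSOMYG00000004695 rose by 6.17 (SE 0.68, adjusted p = 8.35e-10), from 0.807 ± 3.13 to 85.3 ± 52.3 CPM, although DESeq2 gave it an adjusted p of 0.377. Its fold rests on few solvent counts and was 7.17 without replicate 1 and 7.84 against the lowest concentration. ENSOMYG00000027172 fell, with a log2 fold change of -3.26 (SE 0.29, adjusted p = 5.82e-14), from 225 ± 47.4 to 23.0 ± 6.86 CPM. ENSOMYG00000018706 fell as well, with a log2 fold change of -3.36 (SE 0.46, adjusted p = 2.90e-08), from 74.7 ± 21.2 to 6.91 ± 5.04. These 4 IDs were chosen after the data were examined, as the largest changes meeting the rule for named genes apart from its demand for a gene name. The second highest concentration, 19.2, gave 4 genes, or 21 with the plate as a block, and the lowest gave 30, or 150 with the block. The count was 1047 without replicate 2, and 880 against the lowest concentration of dip in place of solvent. The wells of that lowest concentration held 30.8% to 36.5% of the median total of the other wells of their library.

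At its highest concentration of 56.47, met raised 344 genes and lowered 687 of 3795 tested, and 933 of the 1031 changed at least 2-fold. ENSOMYG00000023930 rose here too, by a log2 fold change of 2.84 (SE 0.68, adjusted p = 0.00103), and ENSOMYG00000027172 fell, with a log2 fold change of -5.53 (SE 0.59, adjusted p = 1.13e-10; n = 3 against 24 solvent wells). The second highest concentration, 18.8, gave 12 genes, all higher, and the third 2, against 29 and 13 with the plate as a block. The count depended on single replicates, with 421 genes without replicate 1, and it was lower by more than 1.5 times without replicate 3 as well. It was 679 against the lowest concentration of met and 353 of 818 tested with wells thinned to 48188 counts, where 3 wells under that total were kept as they were.

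The many genes of col were not limited to its highest concentration. The counts were 688 at 3.99, 619 at 1.33, 706 at 0.443 and 619 at 0.148, then 2 at 0.0493 (4 with the plate as a block). The median well held 23.4%, 29.2% and 35.3% of its library's median at 1.33, 0.443 and 0.148. It held 45.6% at 0.0493 and 125% at 0.0164. With wells thinned to at most 77699 counts, 468 of 1624 tested genes were called at the highest concentration. Whether low totals account for part of the counts at the lower ones was not tested. A set of 233 genes was called at all 4 highest concentrations, of which 51 rose and 182 fell at each. Replicate 2 was left out at each of them, so all 4 counts rest on the same 2 replicates and the same solvent wells. The median absolute log2 fold change of these 233 genes was 2.00 at 0.148 and 0.16 at 0.0493. ENSOMYG00000023930 rose by a log2 fold change of 2.50 (SE 0.94, adjusted p = 0.0466), and ENSOMYG00000027172 fell, with a log2 fold change of -3.50 (SE 0.66, adjusted p = 8.01e-05), at the highest concentration. Only 2 wells remained there, and the count was 337 without replicate 1 and 267 without replicate 3, which leaves 1 well that is assumed to vary like the other groups.

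The share of genes that rose or fell depended on the scaling for these 3 chemicals. With DESeq2's size factors, the fold changes lay higher than with TMM by a median log2 of 0.40 for met, 0.30 for col and 0.13 for dip. The split was then 608 higher and 329 lower for met, against 344 and 687. For col it was 376 higher and 215 lower, against 243 and 445, and for dip 928 and 837, against 762 and 944. Of the genes called by both tools, 672 for met, 453 for col and 1596 for dip, 0 had opposite signs in each.

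**Figure D2:**
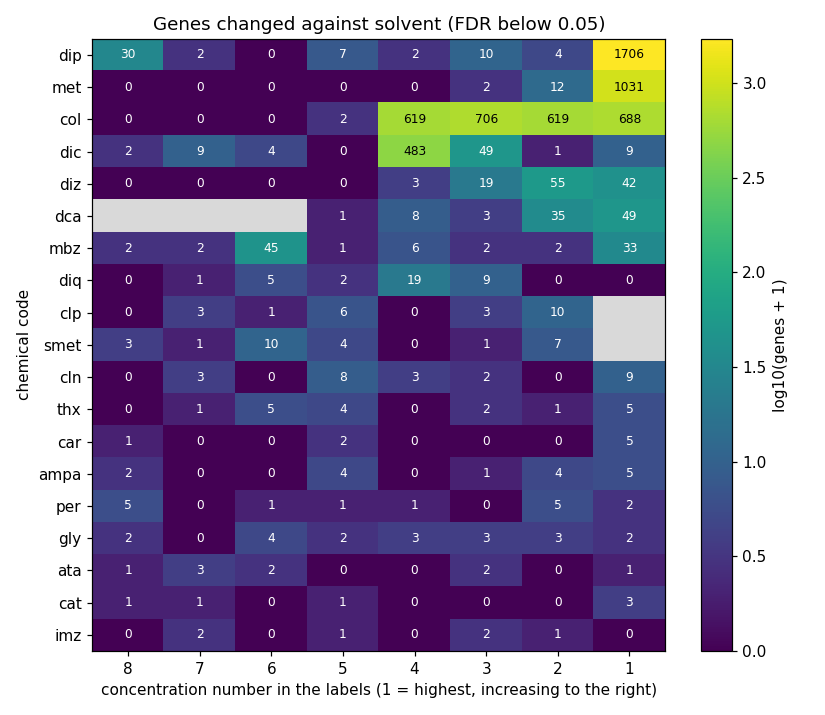
Number of genes changed against solvent (edgeR, FDR below 0.05) for each chemical code and concentration number of the labels, where 1 is the highest; colour is on a log10 scale and grey marks concentrations not tested. The 4 highest concentrations of col each gave 619 genes or more, while dip and met gave 1706 and 1031 at the highest concentration and 30 or fewer at the others.

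The changes of dip resembled those of met and of col, as a comparison chosen after the data were examined showed. Of 3478 genes tested for both dip and met, 252 rose and 516 fell in both, where independent lists would share 57.9 and 165, and 3 changed in opposite directions. Of 2797 genes tested for dip and col, 131 rose and 335 fell in both, where independent lists would share 42.3 and 117, and 13 changed in opposite directions. The log2 fold changes correlated across genes with a Pearson's r of 0.685 and a Spearman's rho of 0.751 for dip and met, and 0.588 and 0.663 for dip and col. Without genes at 0 counts in all treated wells of either chemical, r was 0.731 and 0.661. Genes are not independent replicates; no solvent well is shared, since dip is in batch 2 and met and col are in batch 1. In pairs of single plates, r ranged from 0.338 to 0.686 for dip and met and from 0.467 to 0.590 for dip and col. Both shares of risen and fallen genes move with the scaling given above.

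**Figure D3:**
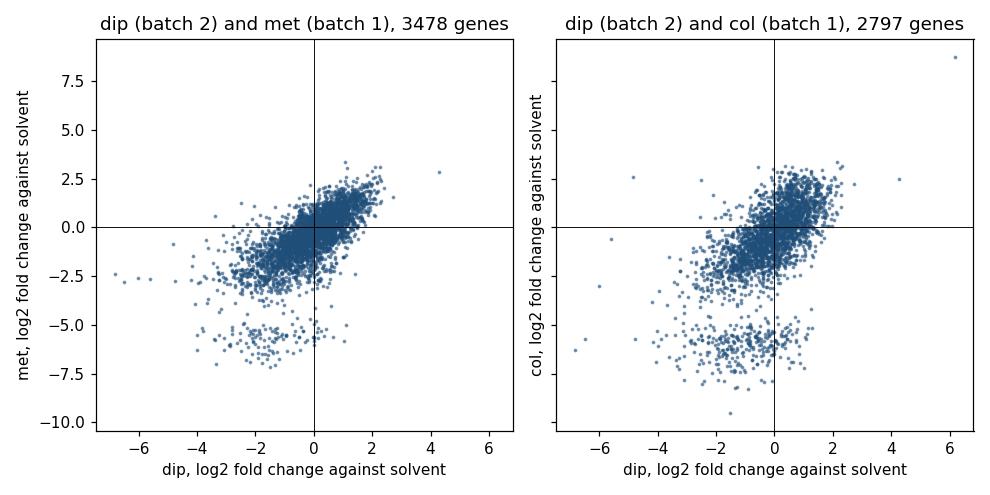
Log2 fold change against solvent of each gene in dip (horizontal axis) and in met or col (vertical axis), at the highest concentration; each point is 1 gene tested in both, 3478 for met and 2797 for col. Points far below the others include genes with 0 counts in the treated wells, whose fitted fold change is no measure of size.

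With diz, 27 genes rose and 15 fell at 52.65, and the count was 55 at 17.55, 19 at 5.85 and 3 at 1.95. With dca, 39 genes rose and 10 fell at 25, and 35 genes changed at 12.5. With mbz, 10 genes rose and 23 fell at 38.14. With the plate as a block, the 4 counts of diz were 108, 112, 44 and 19, and the count of mbz was 75. Without a low-count filter they were 84 for diz, of which 29 rose and 55 fell, and 78 for mbz. With the solvent wells of each plate summed they were 20 for diz, 24 for dca and 17 for mbz. They fell to 11 for diz without replicate 1 and 14 without replicate 3, to 25 and 21 for dca without replicates 1 and 3, and to 8 and 16 for mbz without replicates 1 and 3. Against the chemical's own lowest concentration, the counts were 10 for diz, 2 for dca and 10 for mbz, or 30, 12 and 32 with the plate as a block.

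The remaining chemicals changed few genes, and most of these counts depended on the fit. With the plate as a block, the counts were 41 for clp, 35 for smet, 26 for thx, 25 for per, 19 each for car and cln, 17 for gly, 15 for dic, 10 for ampa, 9 for diq, and 5 each for ata and imz. DESeq2 gave 0 for ampa and ata, where 198 of 4232 and 149 of 3403 tested genes had an unadjusted p under 0.05 in edgeR. In simulated data for ata, 75% of genes changed 4-fold and 11% of genes changed 2-fold were recovered, so most 2-fold changes would be missed under the assumptions of that simulation.

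The second question was where along the dilution series a response starts. Over the 128 lower concentrations tested, the median count was 1 gene, and 116 gave 10 genes or fewer. At 45 of them edgeR called 0 genes, with 68 to 375 genes at an unadjusted p under 0.05; DESeq2 was not run on the lower concentrations. With the plate as a block, the median was 8 genes. Counts did not rise with concentration for every chemical. With dic, 483 genes changed at the fourth highest concentration (90 rose and 393 fell) and 49 at the third, against 1 and 9 at the second and the highest. With mbz, 45 genes changed at the sixth, with dip 30 at the lowest, and with diq 19 at the fourth highest against 0 at the highest and the second. These groups of mbz, dip and diq had the lowest median total of their chemical. Their wells held 27.1% to 31.7% of the library median for mbz, 30.8% to 36.5% for dip and 47.3% to 62.1% for diq. At the third highest concentration of dic, 1 well was left out and the median well held 41.7%. Whether low totals account for these counts was not tested. With the plate as a block, the counts were 86 at the third for dic, 86 at the sixth for mbz, 150 at the lowest for dip and 57 at the fourth highest for diq. The many genes of dic at 1 concentration are weighed below.

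The trend across concentrations was tested within the wells of each chemical, which share their libraries across all concentrations, unlike most chemicals and the solvent wells. Expression followed the concentration step for 836 genes with col (365 rose and 471 fell), 231 with dip (187 and 44), 71 with met (66 and 5), 32 with diz (26 and 6) and 13 with dca (12 and 1). The other counts were 7 for dic, 3 each for cln, mbz and smet, 1 each for car, per and thx, and 0 for ampa, ata, cat, clp, diq, gly and imz, where 96 to 148 genes had an unadjusted p under 0.05 in edgeR and no other tool was run. For dip, 2 of 40 orders of the concentrations, the real one included, gave as many genes, and the highest other gave 265. These orders keep the strongly changed wells of the highest concentration, so they cannot decide on chance for dip. The slope is linear in the concentration step, and 212 of the 1706 genes of dip and 65 of the 1031 of met followed it. Without replicate 1, 2 or 3 the count was 50, 43 or 66 for dip, 11, 21 or 27 for met and 21, 20 or 17 for diz, and for col it was 467 without replicate 3. With the plate as a block, it rose to 29 for dca, 17 for per, 6 each for mbz, smet and thx, 3 for gly and 2 each for car, diq and imz. The split into risen and fallen genes depended on the low-count filter. Without it, the trend had 801 and 1863 for col, 264 and 78 for dip, 60 and 41 for met, 61 and 74 for diz and 11 and 4 for dca.

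Benchmark concentrations were modelled for the trend genes, and the point of departure was the 20th lowest. It was 0.0444 for col (814 genes), 2.71 for diz (31 genes), 11.5 for met (71 genes) and 14.2 for dip (228 genes), in the unit of the labels' concentrations, which is not given. This corresponds to 1.11%, 5.15%, 20.4% and 24.7% of the highest concentration tested. The median benchmark concentration was 0.101 for col, 2.43 for diz, 15.3 for met and 25.4 for dip. For diz, the 20th lowest of 31 genes thus lay above their median. For col the point of departure lay just under the fifth highest concentration, 0.0493, at which 2 genes were called. The total of the median col well also dropped there, from 125% of its library's median at 0.0164 to 45.6% at 0.0493. Those of met and dip lay under their second highest concentrations, 18.8 and 19.2, at which 12 and 4 genes were called. That of dip rests on trend genes for which the orders of the concentrations did not decide on chance. The other chemicals had fewer than 20 genes and no point of departure; dca reached 29 genes and 8.32 with the plate as a block. With a benchmark response of 2 SD in place of 1 SD, the values were 0.0593 for col, 9.80 for diz, 26.7 for met and 29.6 for dip. Without solvent wells in the curves the value for dip was 7.09, and the 10th percentile in place of the 20th lowest gave 0.846 for diz and 6.48 for met. Without single replicates, met moved to 37.8 without replicate 2 and 19.2 without replicate 3, diz moved to 21.4 without replicate 1, and no value was reached for met without replicate 1 or for diz without replicate 2 or 3. The 37.8 and the 21.4 rest on 20 genes each, so each is the highest benchmark concentration of its list. The median benchmark concentrations of these 2 lists were 10.5 for met and 1.85 for diz.

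**Figure D4:**
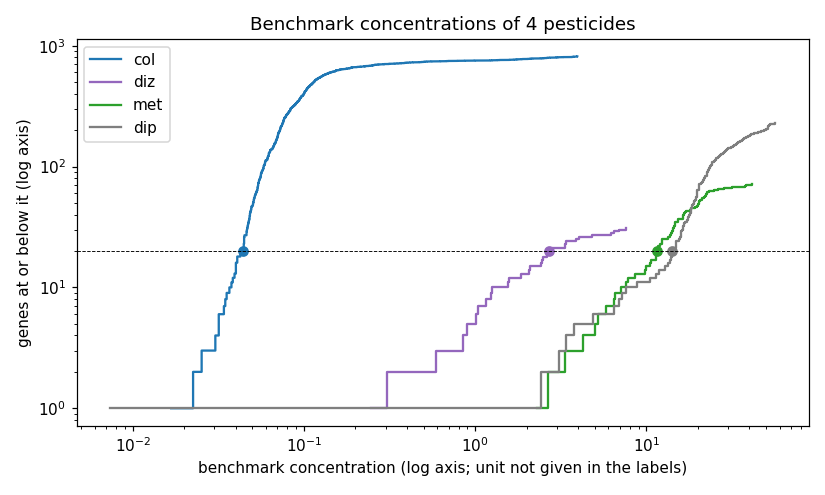
Number of genes at or below each benchmark concentration for col, diz, met and dip (both axes logarithmic, concentration unit not given in the labels). The dashed line marks 20 genes and the filled points the points of departure, 0.0444, 2.71, 11.5 and 14.2.

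As the one chemical run in both batches, dca allowed its effect to be compared between them. Within batch 1, 30 genes changed at the highest concentration and within batch 2, 24. Replicate 2 at that concentration, with 20800 counts, was left out, so batch 1 has 1 treated well fewer than batch 2 in this comparison. Over 3085 genes tested in both batches, 28 and 23 of these were called and 8 were called in both, all with the same sign, where 0.209 would be shared by independent lists. The log2 fold changes correlated across genes with an r of 0.141. The effect differed between batches for 3 genes, all with a smaller rise in batch 2 (edgeR interaction term, FDR below 0.05), and 3 of 40 splits gave as many, so chance could not be excluded. The counts were 16 with the plate as a block (5 higher and 11 lower in batch 2) and 11 with DESeq2 (4 and 7), and 0 without replicate 4 or without replicate 5, with 412 genes at an unadjusted p under 0.05 in the fit of all replicates.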

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

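No test in this part was chosen after its result was seen. The total count of dca replicate 5 at the second highest concentration was 662437, against a median of 288893 for the other 5 wells of that group. Its gap to the nearest well was 0.657 of the group's range. It was the 1 value found in 15 tests of wells that stand apart in groups of 4 to 10, and chance alone gives about 1 in 20.

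The effect of dca differed between batches for 3 genes in the interaction test. Batch 1 has 1 well fewer than batch 2 at the highest concentration, as replicate 2 was left out. The folds below come from a fit within each batch and the differences from the fit of both batches, so they are not exact differences of the folds. ENSOMYG00000038460 rose by a log2 fold change of 3.13 in batch 1 and had 0.33 in batch 2 (difference -2.90, SE 0.56, adjusted p = 0.00402, edgeR). ENSOMYG00000040385 had 2.18 and 0.28 (difference -1.99, SE 0.37, adjusted p = 0.00377). The remaining gene had 3.69 and 1.41, a difference of -2.38. Of 40 splits that exchange wells within plates, 3 gave as many genes as the real one, and the highest other split gave 10, so chance could not be excluded.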

How the results depend on the processing

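Thinning of wells to at most 1 total, removal of the 4 most counted IDs, the block added to the contrast with the lowest concentration, and the block for the lower concentrations were chosen after seeing the data. The other alternatives were planned. The counts below come from edgeR's quasi-likelihood test at a Benjamini-Hochberg FDR below 0.05 unless DESeq2 is named, and each is a count that differed by more than 1.5 times from the reported one. Points of departure are given where they moved by more than 1.5 times or by more than the SD of the values without single replicates, and all of them for diz, which has 1 such value. Where an alternative gave 0 genes, between 62 and 1683 genes had an unadjusted p under 0.05, thinned wells apart. Unless a construction is named, the cause was not tested. Without the 4 most counted IDs, all 19 counts at the highest concentration stayed within 1.5 times of the reported ones.

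With the plate as a replicate block, the counts at the highest concentration rose to 10 for ampa, 5 for ata and imz, 19 for car and cln, 41 for clp, 15 for dic and 9 for diq. They rose to 108 for diz, 17 for gly, 75 for mbz, 25 for per, 35 for smet and 26 for thx. It moved no other count at the highest concentration by as much. The plate block gave 2 for car, diq and imz, 29 for dca, 3 for gly, 6 for mbz, smet and thx and 17 for per for the concentration trend. For the dca effect between batches the block gave 16 genes and DESeq2 gave 11.

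DESeq2 gave 0 for ampa and ata, 1 for diq, 8 for gly, 5 for per and 13 for thx at the highest concentration. Without a low-count filter, which tests many more genes, the counts at the highest concentration were 24 for ampa, 14 for ata, 8 for car, 0 for cat, 19 for dic and thx and 9 for diq and per. They were 84 for diz, 5 for gly, 4 for imz, 78 for mbz and 22 for smet there. The unfiltered trend counts were 120 for ampa, 41 for ata, 43 for car, 35 for cat, 96 for cln and 20 for clp. They were 2664 for col, 29 for dic, 33 for diq, 135 for diz, 53 for gly and 40 for imz as well. The remaining ones were 83 for mbz, 161 for per, 121 for smet and 46 for thx. Summing the solvent wells of each plate, which leaves fewer solvent samples, gave 0 for ampa, ata, cat and gly, 1 for car and per, 2 for cln, 4 for clp, 24 for dca and 20 for diz. That summing also gave 17 for mbz and 3 for thx. With all wells kept, the counts were 1366 for clp (1266 fell), 657 for smet (654 fell) and 20 for thx, where clp and smet then refer to their highest labelled concentration. With the lowest concentration in place of solvent as the control, which has 3 wells at most for a pesticide, the counts were 0 for ampa, ata, car, cat, clp, gly and per, 4 for cln and smet, 2 for dca, 880 for dip, 10 for diz and mbz and 679 for met. This control also gave 3 for thx. Adding the block to that contrast gave 0 for ampa and ata, 1 for cat, clp, diq and gly, 14 for cln, 12 for dca, 973 for dip and 13 for smet. It further gave 61 for thx, and it gave 30 for diz and 32 for mbz, against 10 each without the block. The slope on concentration with the plate as a block is the same fit as the block for the trend above. Here it is set against the counts at the highest concentration, which are another measure. It called 0 for ampa, ata, cat and clp, 2 for car, diq and imz, 4 for cln and 29 for dca. It called 6 for mbz and 2.5e+02 for dip (194 rose and 52 fell), which is within 1.5 times of the 231 trend genes of dip. That slope also called 85 for met and 17 for per. With wells thinned to at most 1 total, which removes counts and leaves wells under that total as they were, the counts at the highest concentration were 1 for ampa, 0 for ata, 5 for cat and cln, 6 for clp, 353 for met and 4 for per. They were 3 for smet after thinning. The thinned trend counts were 546 for col, 7 for dca and 6 for mbz.

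Leaving out each replicate in turn, which lowers the number of wells, gave counts at the highest concentration of 0 to 15 for ampa, 0 to 2 for ata and diq, 0 to 6 for cat, 2 to 9 for cln and 1 to 5 for clp. The counts ranged over 267 to 862 for col, 21 to 45 for dca, 5 to 17 for dic, 1047 to 1415 for dip and 11 to 28 for diz. They spanned 0 to 4 for gly and imz, 8 to 25 for mbz, 421 to 1123 for met, 0 to 7 for per and 3 to 7 for smet. The counts ranged over 0 to 9 for thx. The trend counts ranged over 0 to 1 for ampa, car, clp and thx, 1 to 2 for cln, 467 to 749 for col, 2 to 10 for dic and 43 to 66 for dip. They spanned 0 to 3 for diq, 17 to 21 for diz, 2 to 5 for mbz, 11 to 27 for met and 0 to 9 for per for the trend. Trend counts were 0 to 4 for smet. The count for the dca effect between batches ranged from 0 to 4, with 0 without replicate 4 and without replicate 5. Points of departure, whose unit is not given, ranged over 0.0310 to 0.0401 for col, 16.2 to 18.9 for dip, 21.4 for diz and 19.2 to 37.8 for met. The values of 21.4 and 37.8 are the highest of 20 genes each. No value was obtained for met without replicate 1, or for diz without replicate 2 or 3, because fewer than 20 genes remained. A benchmark response of 2 SD gave 0.0593 for col, 29.6 for dip, 9.80 for diz and 26.7 for met. The 10th percentile gave 0.0558 for col, 0.846 for diz and 6.48 for met. A prior count of 0.5 gave 3.28 for diz. The plate block gave points of departure of 12.0 for dip and 2.52 for diz. Without solvent wells the points of departure were 0.0311 for col, 7.09 for dip and 3.94 for diz.

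At the lower concentrations, numbered as in the labels from 2 downward in concentration, the plate block moved 106 of 128 counts by more than 1.5 times and its median was 8 genes against 1. For ampa it gave 13, 11, 2, 14, 7, 6 and 12 at 2, 3, 4, 5, 6, 7 and 8. For ata it gave 14, 17, 1, 6, 19, 12 and 2 at 2, 3, 4, 5, 6, 7 and 8. For car it gave 4, 10, 8, 5, 17 and 11 at 2, 3, 5, 6, 7 and 8. For cat it gave 6, 4, 9 and 7 at 4, 5, 6 and 8. For cln it gave 15, 17, 9, 33, 8, 20 and 20 at 2, 3, 4, 5, 6, 7 and 8. For clp it gave 28, 5, 13, 7, 7 and 4 at 3, 4, 5, 6, 7 and 8. For col it gave 4, 5, 4 and 4 at 5, 6, 7 and 8. For dca it gave 7 and 2 at 3 and 5. For dic it gave 2, 86, 9, 20, 28 and 10 at 2, 3, 5, 6, 7 and 8. For dip it gave 21, 19, 4, 11, 19, 14 and 150 at 2, 3, 4, 5, 6, 7 and 8. For diq it gave 2, 14, 57 and 13 at 2, 3, 4 and 7. For diz it gave 112, 44, 19, 4 and 2 at 2, 3, 4, 5 and 6. For gly it gave 12, 18, 21, 6, 17, 3 and 6 at 2, 3, 4, 5, 6, 7 and 8. For imz it gave 7, 7, 29, 3, 15 and 2 at 2, 3, 4, 5, 7 and 8. For mbz it gave 8, 13, 28, 86 and 14 at 2, 4, 5, 6 and 8. For met it gave 29, 13, 9, 3, 3 and 5 at 2, 3, 4, 5, 6 and 7. For per it gave 13, 6, 2, 3, 2, 3 and 54 at 2, 3, 4, 5, 6, 7 and 8. For smet it gave 21, 11, 18, 9 and 11 at 3, 5, 6, 7 and 8. For thx it gave 1, 5, 8, 3 and 1 at 3, 4, 6, 7 and 8.

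The log2 fold change of ENSOMYG00000004695 in dip was 6.56 by DESeq2 with an adjusted p of 0.377, against 6.17 and 8.35e-10 by edgeR, and kept its sign and call under each other alternative run, at 7.17 without replicate 1 and 7.84 against the lowest concentration. The values of the other 3 named IDs kept sign and call under every alternative run. The tests of gene lists, with a preset or an estimated correlation and with a block, were not run because no ID matched the reference names. In simulated data, 4-fold changes were recovered for 43% of genes at the highest concentration of col and 88% at that of dca, and 2-fold changes for 6% and 34%. The p-values of the reported fit measure the spread among the wells of a group, within and between plates together. They take the solvent wells of 1 plate as independent, although these share a passage. With 1 summed solvent sample per plate, the counts at the highest concentration were 1406 for dip, 872 for met and 509 for col.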

Other observations

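The splits belong to the fixed procedure. The other tests below were chosen after the results they measure had been seen, except the test of the well row.

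At the fourth highest concentration of dic 483 genes changed, against 49, 1 and 9 at the 3 higher ones. The tables argue against a concentration response, since the median log2 fold change of these genes, signed by their direction, was 1.55 there but 0.34, 0.017 and 0.018 at the 3 higher concentrations. These wells sat at position E10, where all 6 wells of any group held 20800 to 50205 counts; the E10 solvent wells of batch 1 deviated by 0.78 and 1.12 in the direction of the dic genes, against -0.52 to 0.74 in the other solvent wells of that batch. With wells thinned to 41711 counts 28 genes were called, 14 of them among the 483, against 19 at the third highest concentration and 4 or fewer at the others. However, dip thinned to the same total fell from 1706 to 316 with fewer genes tested, so the drop from 483 to 28 decides nothing. The deviation was not limited to E10. It was 0.74 in the solvent well with the lowest total, 25250, then 0.41 at 58704, 0.32 at 86782 and 0.39 at 92131, but -0.073 at 82867. Low totals thus mostly went with it outside E10 too. Whether position adds to it cannot be told, as every E10 well was low, and either may account for the count.

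The like changes of dip, met and col may be a common response of these cells to the highest concentrations, which is a hypothesis found and tested on the same data. Shared solvent wells are argued against by the correlation of dip and met, which share none and had an r of at least 0.338 in each of 9 pairs of single plates. The well row, and pooling apart from the solvent wells, are argued against by the 6 other batch 1 chemicals in row H, whose r with dip was -0.0221 to 0.114. For dip and met, the depth of the wells alone is argued against by their r with each well thinned to 48188 counts. This r was 0.831 over 561 genes, against 0.877 without thinning over the same genes, with 3 solvent wells under that total left out. Thinning evens the depth but leaves any other difference of wells with low totals, so it cannot decide on such a difference. For col, this r was not computed with thinned wells. Solvent wells showed a trend along the rows for 1 of 2864 genes in batch 1 by edgeR (3 with the plate as a block). In batch 2 it was 0 of 3009. An unadjusted p under 0.05 was reached by 61 and 117 genes, and no other tool was run on these wells. The solvent wells of batch 2 lie in rows A to E only. They thus say nothing on row H, where dip had its highest concentration.

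The wells at the highest concentration of clp and smet held 0.712% to 10.2% of the median total of the other wells of their library. A fault of position H04 is argued against by its batch 1 wells, with imz, which held 53.5% to 113%. Position H07 stays open for smet, because its batch 1 wells, with thx, held 13.8% to 26.0%. A loss of cells or RNA at these concentrations may account for the totals and was not tested. With these wells kept, 1366 genes were called for clp, of which 1266 fell, and 657 for smet, of which 654 fell. These wells held 2703 to 22101 counts for clp and 1809 to 4593 for smet.

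The total of a well, relative to its library, followed its position on the plate in both batches. Over 82 positions the mean log2 totals of batch 1 and batch 2 correlated with a Pearson's r of 0.595 and a Spearman's rho of 0.797, each with a two-sided permutation p of 1e-05, the smallest value that the permutations drawn can give. Without the 2 positions farthest from the median r was 0.590. This was the only relation of its kind computed, and row and concentration coincide in both batches.

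Wells were exchanged between the highest concentration and solvent within plates in 40 splits per chemical, the real one included. Only the real split, 1 of 40, gave as many genes for car, cln, clp, dca, dic, dip, diz, mbz, met and smet. That is the smallest share 40 splits can give. It makes chance unlikely for each chemical taken alone but does not exclude it, and no correction was made for the number of chemicals. Most of these chemicals were in other libraries than the solvent wells exchanged with them, so a difference between libraries could give it too. Small counts depended on the fit all the same. With summed solvent wells car fell from 5 genes to 1 and cln from 9 to 2, against 2 and 3 in their highest other splits, and clp fell from 10 to 1 without replicate 3, against 1. The highest other split gave 209 genes for dip, against 1706, and 6 or fewer for the others. For ampa 4 of the 40 splits gave as many genes as the real one, for ata 16, and for cat, gly and per 2 each, so chance could not be excluded for these counts. The splits used the fit without a block and were not run with it, where ampa had 10 genes, gly 17 and per 25. For diq and imz the real count is 0, so their splits, all 40 as large, say nothing. The highest other splits were 6 for ampa, cat and imz, 5 for ata, 2 for gly and per, and 1 for diq. For col and thx, only 2 wells remained at the highest concentration and no splits were drawn.

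For the trend, concentrations were reordered within libraries into 40 orders per chemical, the real one included. Only the real order gave as many genes for cln, col, dca, dic, diz, mbz and met, and the highest other count was 7, for met. Chance is thus unlikely for each taken alone but not excluded, and no correction was made for the number of chemicals. For dip 2 of 40 orders gave as many, the highest other gave 265 genes against 231, and the median of the others was 0. The orders keep the wells of the highest concentration, where 1706 genes changed. An order with these wells near 1 end can thus give a trend too, so the orders cannot decide on chance for dip. Chance could not be excluded for car and thx with 2 orders, smet with 3, and per with 4, where the highest other order gave 3 genes or fewer. The orders were fitted without a block and not run with it, where per had 17 genes and smet and thx 6 each. For ampa, ata, cat, clp, diq, gly and imz the real count is 0, so their 40 orders say nothing.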
